A study of Mus musculus with 8 samples.

How the data were processed

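RNA was measured in leukaemia stem cells of mice with acute myeloid leukaemia driven by HOXA9 and MEIS1. Per the labels' protocols, about 10000 cells that were positive for GFP and c-Kit and negative for Gr-1 were sorted from bone marrow for each library, and cDNA was made with the Smart-Seq V4 ultra-low-input kit. The 8 libraries form 2 groups by the genotype label, 4 wild-type (WT) and 4 Nynrin-KO, with no other factor given. The replicate numbers come from the sample titles. Nothing in the labels says that the libraries of a group came from separate mice, so p-values measure the spread between these libraries.

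The authors deposited one table of 48500 genes with 8 value columns, without naming the unit in the header. The deposited values were read as FPKM, because each value multiplied by the length of the gene's longest GENCODE M21 transcript summed to about the same total in every column. Dividing by a single step per library then gave whole reads for 99.42% to 99.45% of the values checked, with a tolerance of 0.1 read. Per the submitters' processing notes, the genome build was mm10 and the tools named were Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq, with no role given for each. The counting rule, the handling of reads that match several genes and the use of strand are not given in the sources used here. Gene identifiers matched GENCODE M21 (GRCm38, the assembly also called mm10) for 99.62% of the genes, and coordinates, counted from 1, were taken from that annotation.

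The recovered depth ranged 18.1-fold, from 1.83 M reads (M for mega) in KO3 to 33.09 M in WT1. For a transcript of 1 kb, the level that 3 reads give was 1.64 FPKM in KO3 and 0.0907 FPKM in WT1. These floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

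Because the unit is FPKM, the branch of the test plan for normalized values was used. Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with the group as the only term, moderated variances with trend and robust estimation, a two-sided test, and Benjamini-Hochberg adjustment at 0.05. A gene can pass this filter through the 4 libraries of 1 group alone, which favours a difference between the groups. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low level. Every adjusted p of a gene is from limma. The 38 gene lists were fixed in advance, and the 36 with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The lists cover redox, metabolism, apoptosis, translation, stress, cell cycle, stem cell, interferon, inflammatory and cell type genes. Nynrin, Txnip and library composition were also tested with exact two-sided permutation tests over the 70 arrangements of 4 against 4, where the smallest possible p is 0.0286. Permutations, composition and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

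Genes are named by a rule fixed before the data were examined. It takes Nynrin, Txnip, Hoxa9, Meis1, Kit, Ly6g, Bcl2 and Mcl1, and the 10 largest rises and 10 largest falls among genes past the threshold. These last genes must have groups that do not overlap and a mean of at least 5 FPKM in the higher group, and unnamed gene models are left out. For each list past the threshold, or with at least 2 members past it, up to 4 members with the smallest p are named, and for other lists at most 2. S100a8, S100a9, Gm10800, Eef1a1, Ear2 and the Y-linked genes fall outside this part of the rule. So do the further mature neutrophil genes named for their ratio to S100a8, and the genes named from the MHC class I group. Apart from the Y-linked genes, which were fixed as signs of the sex of each mouse, all these genes were chosen for naming after their values were seen.

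The fit was tested on simulated values with the real means, spreads and depths. For the comparison of Nynrin-KO with WT, limma called 17.3% of 98 genes changed 2-fold and 65.6% of 96 genes changed 4-fold, with 2 false calls among 11364 genes. The simulated changes covered a far smaller share of the genes than the 27.9% called in the real data. The adjustment is stricter where few genes change, so these detection rates may be too low for the real comparison.

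Alternatives fixed in advance covered the pseudocount, the filter, scaling, limma's options, sample weights, the replicate number as a block, each library left out, the thresholds and the list test. Alternatives chosen after seeing the data were voom with quality weights on the recovered reads, the libraries WT1 and KO1 or WT3 and KO3 left out, the mean level of the mature neutrophil genes or the level of Gm10800 as a covariate, and the 5 libraries with at least 10000 FPKM of Gm10800 alone. The alternatives planned for count data were not run because the deposited values are FPKM.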

Results

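The comparison asked how the transcriptome of leukaemia stem cells differs when Nynrin, a gene whose product carries a NYN ribonuclease domain, is knocked out. The title of the series links the gene to the redox regulator TXNIP and to resistance to venetoclax, an inhibitor of BCL2. Expression was measured by RNA-seq as FPKM in 4 WT and 4 Nynrin-KO libraries, named here WT1 to WT4 and KO1 to KO4. The WT libraries held 33.09, 7.08, 1.96 and 17.24 M recovered reads, and the Nynrin-KO libraries 9.48, 23.06, 1.83 and 28.7 M. The groups did not differ detectably in depth (14.8 ± 13.7 against 15.8 ± 12.3 M, SD, n = 4 each, exact permutation p = 0.914).

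Nynrin itself (ENSMUSG00000075592, mm10 chromosome 14, 55854010 to 55874736) was low in both groups with no detectable difference, so its level does not check the genotype labels. Its level was 0.008, 0.226, 0.271 and 0.286 FPKM in WT1 to WT4, from 2, 12, 4 and 37 reads. In KO1 to KO4 it was 0.169, 0.0982, 0.437 and 0.121 FPKM, from 12, 17, 6 and 26 reads. It lay below the level of 3 reads in WT1 (0.0121 FPKM) and above that level in the other 7 libraries, the Nynrin-KO libraries included. The means of 0.198 ± 0.129 and 0.206 ± 0.157 FPKM (SD, n = 4 each) differed by 0.008 on the log2 scale (exact two-sided permutation p = 0.914). The gene did not pass the filter on low values and was not tested with limma. Which part of the gene was deleted is not given in the sources used here, and reads from parts left in place would still be counted.

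Sex-linked genes separated the groups almost completely. Xist, the RNA of the inactive X chromosome, stood at 15.2 to 26.5 FPKM in the WT libraries and at 0.0175 to 0.366 FPKM in KO2, KO3 and KO4. The Y-linked gene Ddx3y was at most 0.111 FPKM in WT and 18.2 to 20.7 FPKM in KO2, KO3 and KO4. KO1 held both, with 12.7 FPKM of Xist and 2.18 FPKM of Ddx3y. The sum of 4 Y-linked genes in KO1 was 11.8% of the mean of KO2 to KO4, and its Xist level was 68.0% of the WT mean. Sex and genotype therefore coincide in 7 of the 8 libraries, and the tests below cannot separate them.

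Large parts of the transcriptome differed between the groups. Of 12524 genes tested with limma, 3488 (27.9%) were genes changed at an adjusted p under 0.05, with 1754 higher and 1734 lower in Nynrin-KO. Of the 10 largest rises 4 were of listed interferon-stimulated genes, namely Ifi27l2a, Oas1a, Ifit3 and Irf7, and the largest falls included the prostaglandin-degrading enzyme Hpgd and the progenitor surface protein Cd34. Groups did not overlap for 31.7% of the genes tested, where chance gives 2.9%. The first principal component, with 48.4% of the variance, placed WT between -66.5 and -26.5 and Nynrin-KO between 42.5 and 56.9. Annotated pseudogenes made up 452 of the genes that fell and 39 of those that rose, out of 1787 tested.

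**Figure D1:**
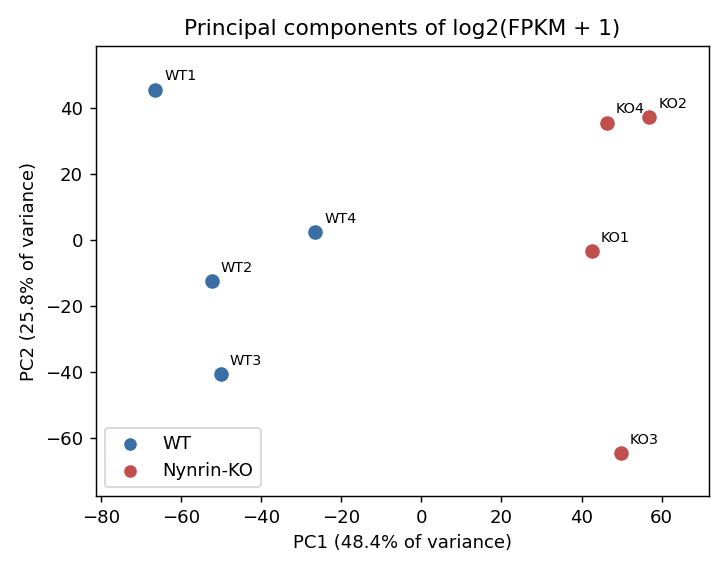
Each point is a library, placed by its scores on the first (x axis, 48.4% of variance) and second (y axis, 25.8%) principal components of log2(FPKM + 1) over 12524 genes, blue for WT and red for Nynrin-KO. The groups part along the first component, and WT1, KO2 and KO4 lie at the top of the second at 45.6, 37.2 and 35.6.

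The libraries also split on the level of Gm10800, in a way that crosses the groups, and the source of its reads was not tested. Gm10800, a gene model resembling satellite repeats, stood at 6076 FPKM in WT1, 3349 in KO2 and 3990 in KO4, and between 28610 and 142300 FPKM in the other 5 libraries. The 3 libraries with a low level are also the deepest, at 33.09, 23.06 and 28.7 M reads, and the other 5 hold 1.83 to 17.24 M, so level and depth go together. Within those 5 libraries limma gave 925 genes changed, with 211 genes higher in Nynrin-KO and 714 genes lower in Nynrin-KO. The set is smaller, with WT2, WT3, WT4, KO1 and KO3, so fewer calls can also come from fewer libraries. With the Gm10800 level as a covariate over all 8 libraries, 4570 genes changed. Of these, 3376 were among the main calls, all in the same direction. The 3 libraries with a low level hold a single WT library, so no test was made within them. Mature neutrophil genes took 4.47% ± 3.2 of the reads in WT and 14.6% ± 4.68 in Nynrin-KO (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible), although cells positive for Gr-1 had been gated out. With the mean level of these genes as a covariate, which largely follows the group, only 10 genes changed.

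Interferon-stimulated genes rose together in Nynrin-KO. Of 22 measured members 21 rose and none fell, with a median log2 change of 3.08, and 22 rose when adjusted over the list alone. Ifi27l2a went from 48.2 ± 72.4 to 1109 ± 920 FPKM (SD, n = 4 each, log2 change 5.24, SE 0.91, adjusted p = 0.00459). The antiviral oligoadenylate synthetase genes Oas1a, Oas1g and Oas2 rose by 4.64, 5.22 and 3.95 on the log2 scale, although reads may be shared between the related genes Oas1a and Oas1g. Ifit1, Ifit3, Ddx58, which encodes the RNA sensor RIG-I, and Irf7, a transcription factor of the interferon response, rose by 3.82, 4.32, 2.93 and 4.15. Oas1g, Rtp4 and Ifi213 are outside the list, and Rtp4 and Ifi213 rose by 4.74 and 4.51. Camera called the list (adjusted p = 5.83e-11), and the adjusted p = 0.449 with an estimated correlation. WT4 stood apart from the other WT libraries, with a mean level of 3.58 against 1.19 to 2.16 in WT1 to WT3 and 4.49 to 6.54 in Nynrin-KO. Without WT1 and KO1, 18 members rose. Within the 5 libraries high in Gm10800 5 rose, and camera still called the list (median log2 change 2.47, adjusted p = 7.52e-11).

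**Figure D2:**
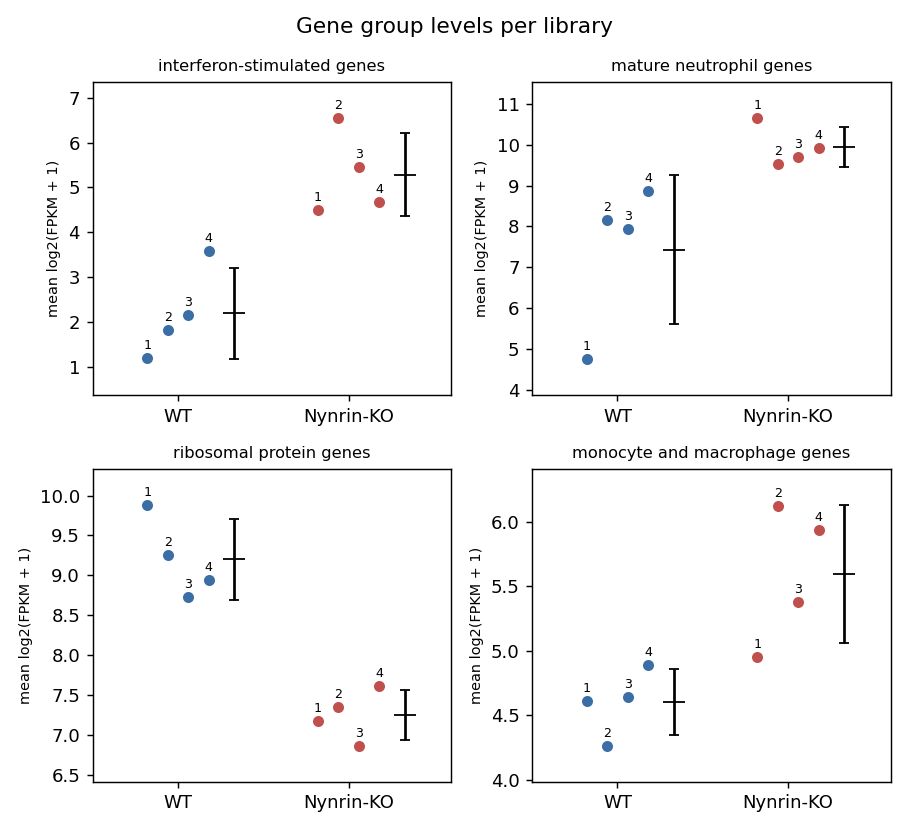
Each panel plots the mean log2(FPKM + 1) of one gene group (y axis) in each library, numbered by replicate, with bars for the mean and SD of 4 libraries. Interferon-stimulated genes lie at 1.19 to 3.58 in WT and 4.49 to 6.54 in Nynrin-KO, and ribosomal protein genes at 8.72 to 9.88 and 6.86 to 7.61.

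Some inflammatory and immediate-early genes also rose. Of 15 NF-kB and inflammatory genes 7 rose and none fell, and 9 rose when adjusted over the list alone. The cytokine gene Il1b went from 1.92 ± 1.35 to 22.1 ± 10.1 FPKM, and the chemokine genes Cxcl2 and Ccl4 and the apoptosis inhibitor gene Birc3 rose by 2.83, 1.64 and 1.61 on the log2 scale. Of 15 immediate-early genes 7 rose, among them Nr4a1, Klf2, Socs3 and Zfp36, by 1.93, 1.51, 1.56 and 1.56, and 7 rose when adjusted over the list alone. The number of immediate-early genes that rose was 4 without WT1 or WT2 and 3 without KO2 or KO4. Both lists were called by camera (adjusted p = 0.000138 and 0.00328), with adjusted p = 0.449 and 0.488 with an estimated correlation. Within the 5 libraries high in Gm10800, 0 of the NF-kB genes and 1 immediate-early gene rose. There camera still called the NF-kB list (median log2 change 0.60, adjusted p = 0.00401) but not the immediate-early list (median log2 change 0.31, adjusted p = 0.052).

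Genes of mature neutrophils were higher in Nynrin-KO, with the share of reads given above. Of 17 measured members 10 rose and none fell, with a median log2 change of 2.40, and 15 rose when adjusted over the list alone. Ly6g, which encodes part of the Gr-1 antigen used in the sort, went from 30.4 ± 20.9 to 183 ± 70 FPKM (log2 change 3.23, adjusted p = 0.0381), and stood at 0.707 FPKM in WT1. The granule protein gene Retnlg went from 51 ± 50 to 809 ± 663 FPKM, and Wfdc21, the chemokine receptor gene Cxcr2 and the G-CSF receptor gene Csf3r rose by 3.99, 1.86 and 1.89 on the log2 scale. S100a8, the most abundant member, was 1288 FPKM in WT1 and 26206 to 45965 FPKM in WT2 to WT4, and 58606 to 128920 FPKM in Nynrin-KO (adjusted p = 0.0975, not passed). Camera called the list (adjusted p = 9.03e-06), with adjusted p = 0.488 with an estimated correlation. The number that rose was 13 without WT1, 5 without WT2, KO1, KO2 or KO4, 6 without KO3, 8 without WT1 and KO1 and 5 without WT3 and KO3. Within the 5 libraries high in Gm10800 6 rose (median log2 change 1.54), and camera still called the list (adjusted p = 1.97e-10).

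Some markers of other blood cells rose as well, several of them at low level. Of 19 monocyte and macrophage genes 7 rose and 2 fell, and 10 rose and 2 fell when adjusted over the list alone. The complement genes C1qa, C1qb and C1qc rose by 2.77, 2.76 and 2.30, and the adhesion gene Vcam1 went from 3.36 ± 1.62 to 64 ± 39 FPKM. Apoe, a lipid carrier made by macrophages, went from 6.48 ± 2.94 to 235 ± 162 FPKM. Of 5 mast cell and basophil genes 3 rose, namely Hdc, Ms4a2 and Cpa3, from 2.84 to 28.3, 0.162 to 5.12 and 1.39 to 27.6 FPKM, and the same number rose when adjusted over the list alone. Ms4a2 passed the filter on low values through the 4 Nynrin-KO libraries alone. Only 3 members of the mast cell and basophil list passed it without KO1 or KO3, so the filter bears on this list too. All 3 measured erythroid genes, Hbb-bs, Hba-a1 and Car2, rose to 7.79 ± 5.96, 6.23 ± 6.42 and 3.01 ± 1.31 FPKM, also when adjusted over the list alone, and Hbb-bs was listed at 0 in 3 WT libraries. Of 16 listed erythroid genes only these 3 passed the filter on low values, each through the 4 Nynrin-KO libraries alone. Their rise and the camera call of the erythroid list were therefore largely set by the filter. KO1 carries much of both globin means, with 15.8 FPKM of Hbb-bs against 2.35 to 8.72 in KO2 to KO4, and 15.7 FPKM of Hba-a1 against 2.11 to 4.79. These lists were called by camera (adjusted p = 0.0047, 0.0047 and 0.0119), with adjusted p = 0.488, 0.449 and 0.449 with an estimated correlation. Without WT1 and KO1, 7 of 18 monocyte and macrophage genes and 2 of 3 mast cell and basophil genes that passed the filter rose, while no erythroid gene passed the filter once any Nynrin-KO library was left out, so that list was not tested there. Within the 5 libraries high in Gm10800 the monocyte and macrophage list was not called (median log2 change 0.21, adjusted p = 0.248), with 4 members that rose and 2 that fell.

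Genes of the translation machinery fell in Nynrin-KO. All 22 listed ribosomal protein genes fell, by a median of 1.99 on the log2 scale, and 22 fell when adjusted over the list alone. Rpl4 went from 2740 ± 840 to 636 ± 159 FPKM (SD, n = 4 each, adjusted p = 0.00174), and Rpl5, Rps2 and Rpl3 fell with log2 changes of -2.16, -2.40 and -2.17. Of 20 MYC and ribosome biogenesis genes 19 fell and none rose, with a median log2 change of -1.42, and 19 fell when adjusted over the list alone. The nucleolar protein gene Npm1 went from 562 ± 239 to 93.6 ± 14.8 FPKM, and Srm, Nop16 and Wdr43 fell with log2 changes of -2.50, -1.73 and -1.53. Camera called both lists (adjusted p = 7.09e-14 and 1.20e-10), each with adjusted p = 0.449 with an estimated correlation. Within the 5 libraries high in Gm10800, 22 ribosomal protein and 12 ribosome biogenesis genes fell, and without WT1 and KO1 22 and 14 fell. The share of summed FPKM from all ribosomal protein genes was 7.21% ± 3.33 in WT and 1.71% ± 0.485 in Nynrin-KO (exact permutation p = 0.0286, 0.0714 after adjustment over 5 measures). Of the other measures, haemoglobin genes took 0.000382% and 0.00277% (adjusted exact p = 0.0714), the 10 highest genes 37.6% and 51.3% (0.0952), and mitochondrially encoded mRNAs 7.81% and 7.25% (0.75), while 10560 to 16342 genes in WT and 11274 to 20443 in Nynrin-KO stood at 1 FPKM or more, with no difference past the threshold. Ribosomal protein genes share sequence with many processed pseudogenes, so their single values are uncertain.

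Part of the genes of proliferation fell. Of 21 G1/S and DNA replication genes 10 fell and none rose, and 11 fell when adjusted over the list alone. The replicative helicase genes Mcm2, Mcm3 and Mcm6 fell with log2 changes of -1.21, -1.52 and -1.80, and Mcm7 went from 88.7 ± 42.1 to 26.9 ± 7.28 FPKM. Of 12 replication-dependent histone genes 7 fell, including H2ac8, H4c4, H2ac4 and H2ac6, with log2 changes of -1.85, -1.55, -1.73 and -1.16, and 8 fell when adjusted over the list alone. Of 21 G2/M and mitosis genes 3 fell, namely Aurkb, Ube2c and Ccnb1, and 1 fell when adjusted over the list alone, with 1 that fell without WT2, KO1 or KO2 and 8 without KO4. Of 11 CDK inhibitor and quiescence genes 6 rose and none fell, also when adjusted over the list alone, with Cdkn1b, Tob1, Rb1 and Btg1 up by 0.80, 0.88, 0.75 and 1.08. The 4 lists were called by camera (adjusted p = 4.18e-05, 0.000691, 0.0259 and 0.0342), with adjusted p = 0.488, 0.449, 0.632 and 0.488 with an estimated correlation. Without WT1 and KO1 the counts were 5 G1/S, 6 histone and 1 G2/M genes that fell and 1 quiescence gene that rose. Within the 5 libraries high in Gm10800 the quiescence list was not called (adjusted p = 0.122) and 0 members rose, and it was not called with Gm10800 as a covariate. In those 5 libraries 4 G1/S, 3 histone and 0 G2/M genes fell, and camera still called these lists (adjusted p = 0.000151, 0.00101 and 0.0258).

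Most nuclear-encoded genes of the respiratory chain and part of the glycolysis genes fell. Of 29 nuclear-encoded respiratory chain genes 20 fell and none rose, with a median log2 change of -1.04, and 26 fell when adjusted over the list alone. The ATP synthase genes Atp5b and Atp5a1 went from 1473 ± 513 to 327 ± 97.8 FPKM and from 478 ± 197 to 115 ± 34.8 FPKM, and Cox5a and Atp5g1 fell with log2 changes of -1.64 and -1.69. None of the 13 mitochondrially encoded mRNAs passed the threshold of limma, and 1, mt-Nd6, had an unadjusted p under 0.05 (log2 change 0.58, adjusted p = 0.0622, camera adjusted p of the list = 0.839). Of 18 glycolysis genes 9 fell and 1 rose, and 10 fell and 2 rose when adjusted over the list alone. Pgam1 went from 868 ± 261 to 138 ± 42.8 FPKM, and Ldha, Tpi1 and Gapdh, the last with many processed pseudogenes, fell with log2 changes of -1.68, -1.72 and -1.55. Camera called the respiratory chain and glycolysis lists (adjusted p = 8.28e-10 and 0.00627), with adjusted p = 0.488 and 0.530 with an estimated correlation. The number of respiratory chain genes that fell was 13 without WT2 or KO1, and without WT1 and KO1 9 of them and 4 glycolysis genes fell. Within the 5 libraries high in Gm10800 11 and 6 fell, with median log2 changes of -1.125 and -0.982. Camera still called both lists there (adjusted p = 1.2e-10 and 0.00142). The number of glycolysis genes that rose was 2 without KO3.

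Txnip (ENSMUSG00000038393, mm10 chromosome 3, 96557957 to 96561883), which encodes the inhibitor of thioredoxin, did not pass the threshold. Its level was 74.5 ± 11.5 FPKM in WT and 130 ± 51.6 FPKM in Nynrin-KO (SD, n = 4 each), a log2 change of 0.72 (SE 0.29, adjusted p = 0.0966, exact two-sided permutation p = 0.0857). The 3 libraries KO2, KO3 and KO4 stood above every WT library, at 194, 96.8 and 148 FPKM, and KO1 was within the WT range at 80.4 FPKM. KO1 is also the library that held both Xist and Y-linked reads, so sex and genotype cannot be told apart for Txnip. The call depends on the processing: Txnip passed under quantile normalization (log2 change 1.16, adjusted p = 0.00454), array weights (0.92, 0.0242) and voom on recovered reads (0.75, 0.0359), and the adjusted p of the Txnip log2 fold change ranged from 0.00454 to 0.467 over the alternatives. Of 7 genes of the arrestin-domain and MondoA list, which includes Txnip, 2 rose, Arrdc4 by 1.63 and Arrdc3 by 1.10, and 5 rose when adjusted over the list alone, with 4 that rose without KO3. Of 9 HECT ubiquitin ligase and adaptor genes 3 rose, also when adjusted over the list alone. Nedd4 went from 0.898 ± 0.22 to 9.2 ± 1.98 FPKM, Ndfip2 and Smurf2 rose by 0.80 and 0.54, and Itch, known to ubiquitinate TXNIP, was 12.1 ± 1.26 and 17.6 ± 4.79 FPKM (adjusted p = 0.116). Both lists were called by camera (adjusted p = 0.0303 and 0.0321), with adjusted p = 0.488 and 0.449 with an estimated correlation, and without WT1 and KO1 1 member of each rose. Within the 5 libraries high in Gm10800 neither was called (median log2 changes 0.27 and 0.26, adjusted p = 0.304 and 0.184) and 0 members rose, and neither was called with Gm10800 as a covariate.

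Part of the redox genes fell. Of 22 thioredoxin, peroxiredoxin and glutathione enzyme genes 8 fell and 3 rose, and 10 fell and 3 rose when adjusted over the list alone. The superoxide dismutase gene Sod1 went from 136 ± 36.3 to 29.5 ± 11.8 FPKM, and Glrx3, Gpx1 and Prdx4 fell with log2 changes of -1.31, -0.83 and -1.64, while without WT1 and KO1 3 members fell and 0 rose, as within the 5 libraries high in Gm10800. The number that rose was 1 without WT1, WT3, KO1 or KO4, and the number that fell was 4 without WT1 or KO1. Camera called the list (adjusted p = 0.0191), with adjusted p = 0.488 with an estimated correlation, but not with quantile normalization or with the neutrophil score as a covariate. Of 14 NRF2 target genes 2 rose and 1 fell, the same numbers as when adjusted over the list alone, and camera did not call the list (adjusted p = 0.981). Of these, 0 fell without any 1 library except WT3, where 2 fell, and KO4, where 1 fell. The haem oxygenase gene Hmox1 went from 13.8 ± 5.75 to 74.7 ± 34.2 FPKM, Osgin1 rose by 1.46 and Gstm1 fell by 0.81. Of 11 ferroptosis and iron genes 2 rose, Hmox1 and the iron exporter gene Slc40a1, which went from 1.09 ± 0.578 to 14.7 ± 2.15 FPKM, and 2 rose when adjusted over the list alone (camera adjusted p = 0.844).

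Bcl2 fell and Mcl1 rose. Bcl2 (ENSMUSG00000057329, mm10 chromosome 1, 106538178 to 106714274), which encodes the target of venetoclax, went from 9.23 ± 2.45 to 1.43 ± 0.686 FPKM (SD, n = 4 each, log2 change -2.09, SE 0.25, adjusted p = 0.00157). Mcl1 (ENSMUSG00000038612, mm10 chromosome 3, 95658788 to 95663176), a related survival gene, went from 10.5 ± 2.04 to 28.3 ± 9.06 FPKM (log2 change 1.32, SE 0.24, adjusted p = 0.00493). Of 10 anti-apoptotic genes 7 rose and 1, Bcl2, fell, and 7 rose and 2 fell when adjusted over the list alone. The number that rose was 4 without KO2. Bcl2a1d, whose reads can be shared with near-identical copies, rose by 2.40. Camera called the list (adjusted p = 0.0137), with adjusted p = 0.449 with an estimated correlation, and without WT1 and KO1 3 members rose and the list was not called (adjusted p = 0.0583). Within the 5 libraries high in Gm10800 it was not called either (adjusted p = 0.111), with 0 of 8 members that rose. Of 16 pro-apoptotic genes 3 rose and 3 fell, the same numbers as when adjusted over the list alone. The death receptor gene Fas went from 2.39 ± 1.25 to 16.3 ± 2.46 FPKM, Bcl2l11, which encodes BIM, rose by 0.70, and the cytochrome c gene Cycs fell by 1.72 (camera adjusted p = 0.790). Of 19 p53 target genes 4 rose and 2 fell, with Trp53inp1 and Btg2 up by 1.76 and 1.05 and Bax down with a log2 change of -1.40, and 4 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.788). In the p53 list 2 rose without WT1, WT2, KO2 or KO4, and 1 fell without WT1, WT2, KO1 or KO2.

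**Figure D3:**
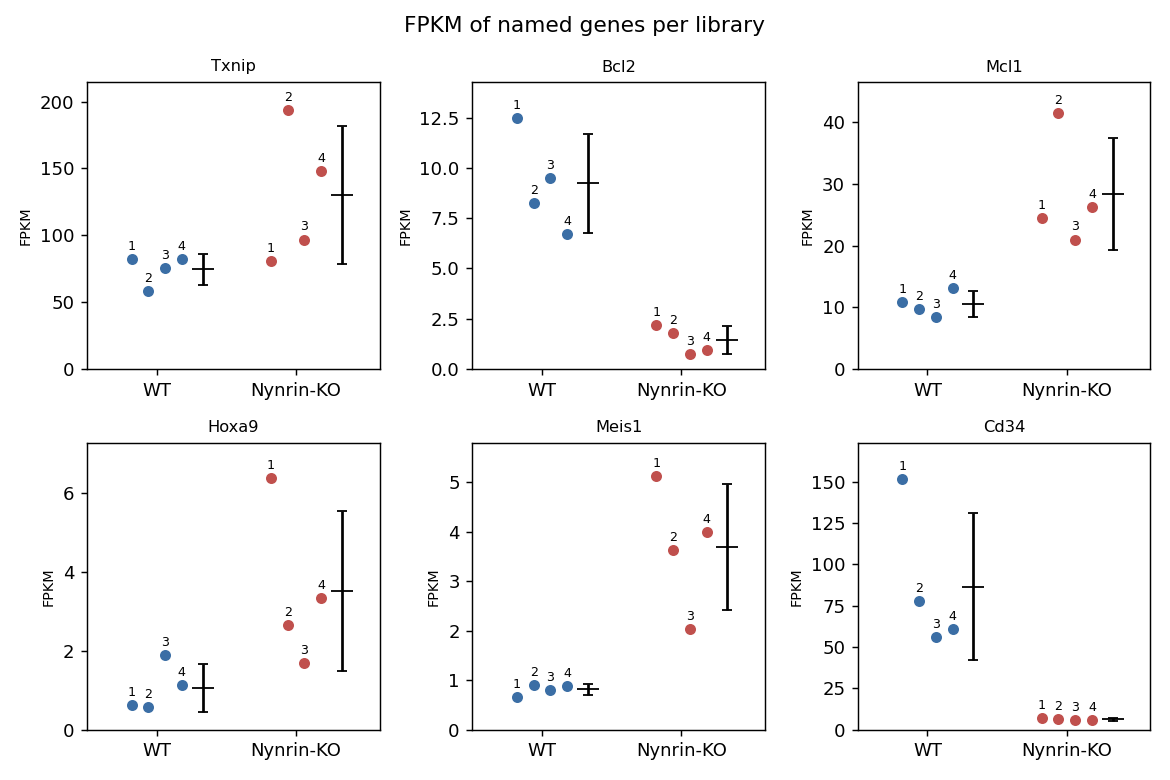
Each panel plots the FPKM (y axis, from 0) of one gene in each library, numbered by replicate, with bars for the mean and SD of 4 libraries. Bcl2 lies at 6.70 to 12.5 FPKM in WT and 0.761 to 2.20 in Nynrin-KO, Mcl1 has means of 10.5 and 28.3 FPKM with no overlap, and the Txnip values overlap.

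Reads assigned to the transcription factor genes that drive this leukaemia were higher in Nynrin-KO, at low level. Hoxa9 went from 1.06 ± 0.614 to 3.52 ± 2.02 FPKM (log2 change 1.08, adjusted p = 0.0397), and Meis1 from 0.816 ± 0.109 to 3.69 ± 1.28 FPKM (log2 change 1.33, adjusted p = 0.00466). The groups overlapped for Hoxa9, with 1.90 FPKM in WT3 and 1.70 FPKM in KO3. Meis1 lay at 0.664 to 0.898 FPKM in WT and passed the filter on low values through the Nynrin-KO libraries alone. Whether the reads of Hoxa9 and Meis1 come from the endogenous genes or from a transgene is not given in the sources used here. Of 15 genes of the HOXA9 and MEIS1 programme 6 rose and 4 fell, also when adjusted over the list alone, with Pim1 and Camk2d up by 1.23 and 1.98 (camera adjusted p = 0.410), and 2 fell without KO1. Kit, the sort marker, was 4.92 ± 1.61 and 3.73 ± 0.89 FPKM (adjusted p = 0.405, not passed). Of 13 stem and progenitor genes 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.189), and 1 rose without KO2. Cd34 went from 86.4 ± 44.3 to 6.26 ± 0.756 FPKM and Gata2 fell by 1.06, while Ly6a, an interferon-responsive stem cell marker, and Cd44 rose by 3.09 and 0.79. Of 15 primary granule genes 6 rose and 4 fell, and 8 rose and 4 fell when adjusted over the list alone. Nkg7 and Ms4a3 rose by 5.14 and 3.49, Ctsg fell by 1.96 and Calr fell by 2.67 (camera adjusted p = 0.153).

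Other large falls were of Hpgd, from 1204 ± 440 to 15.6 ± 10.9 FPKM, the galectin gene Lgals1, from 1546 ± 409 to 168 ± 52 FPKM, and the cytokine gene Mif, from 424 ± 225 to 46.6 ± 14.9 FPKM. Slc4a8 and Erdr1 fell with log2 changes of -3.85 and -2.81, although the reads of Erdr1, a repeated gene of the sex chromosomes, are hard to place. Phgdh and Psat1, enzymes of serine synthesis, fell with log2 changes of -2.84 and -2.38, and Shmt2 fell by 2.32, while Asns rose by 1.34. These 4 belong to the ATF4 and amino acid list, of which 4 of 14 fell and 2 rose, and 5 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.153). Of 13 unfolded protein response genes 5 fell, including Hsp90b1, Manf, Pdia6 and Hspa5, and 6 fell and 1 rose when adjusted over the list alone, with 3 that fell without WT2, KO1 or KO2. Of 9 heat-shock genes 5 fell, or 3 without WT1, WT2 or KO1, also when adjusted over the list alone, with Hspd1, Hspe1, Hsp90aa1 and Hspa8 down with log2 changes of -2.17, -1.68, -1.34 and -0.99. Camera called both (adjusted p = 0.0207 and 0.0259), with adjusted p = 0.517 and 0.556 with an estimated correlation, and without WT1 and KO1, where neither list was called, 1 and 3 members fell. Neither was called with array weights, without WT3 and KO3 or with the neutrophil score as a covariate, and the unfolded protein list was not called with quantile normalization. With the neutrophil covariate the median log2 changes were -0.619 and -0.722, against -0.72 and -0.818 in the main fit. The median SEs grew from 0.245 and 0.282 to 0.348 and 0.378.

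Among the remaining lists, 6 of 19 NYN-domain ribonuclease and mRNA decay genes rose, also when adjusted over the list alone, including N4bp1, Zc3h12d and Zfp36l1, by 1.26, 1.41 and 1.05. Of 23 autophagy and lysosome genes 5 rose, with Wipi1, Atg7 and Map1lc3b up by 1.11, 0.90 and 0.75, and Lamp1 fell by 0.97, the same numbers as when adjusted over the list alone. Camera called both (adjusted p = 0.0119 and 0.0207), with adjusted p = 0.488 and 0.611 with an estimated correlation, and without WT1 and KO1 2 and 0 members rose. In the mRNA decay list 3 rose without KO1, KO2 or KO4, and in the autophagy list 2 rose without WT1, WT2 or WT3 and 1 without KO1, KO2 or KO4. Neither was called within the 5 libraries high in Gm10800 (median log2 changes 0.15 and 0.23, adjusted p = 0.158 and 0.129), where 0 members of both rose, and the autophagy list was not called with Gm10800 as a covariate. Of 15 FOXO target genes 6 rose, also when adjusted over the list alone, with Ccng2 up by 0.86 (camera adjusted p = 0.0806). Of 8 MHC class II and dendritic cell genes 2 rose, H2-Aa and H2-Eb1, and H2-DMb1 fell by 1.03, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.185). In this list 0 rose without WT1, WT2, KO2 or KO4 and 4 without KO3, and 0 fell without WT1, WT2, WT3, WT4 or KO1. Of 6 B cell genes 2 rose, Cd79a and Vpreb3, and 3 rose when adjusted over the list alone (camera adjusted p = 0.117), but 1 rose without WT1 or KO1 and 0 without KO2, KO3 or KO4, where fewer members passed the filter. Of 3 megakaryocyte genes 1, Pf4, rose, also when adjusted over the list alone (camera adjusted p = 0.449), but 0 rose without WT1 or any 1 Nynrin-KO library and 2 rose without WT2. The T and NK cell list had 1 measured member, Gzma, which rose but not without WT1, and the stromal and endothelial list had 2, of which Pecam1 fell by 1.62, so these lists were not tested. The median and the direction of camera differed in sign for the pro-apoptotic, p53 and mitochondrially encoded lists, and the mean did for the NRF2 list.

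**Figure D4:**
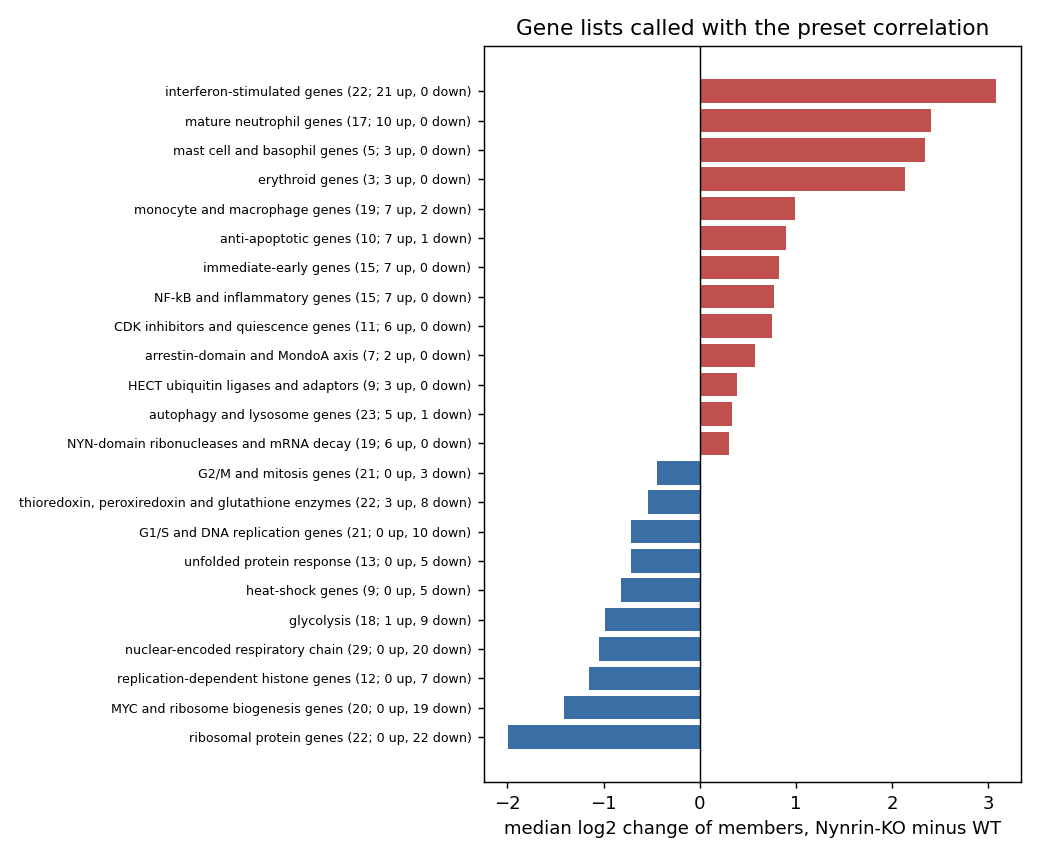
Bars give the median log2 change of the members (x axis, Nynrin-KO minus WT) of the 23 gene lists called with the preset correlation, with the number measured and the numbers that rose and fell beside each name. The medians run from -1.99 for ribosomal protein genes to 3.08 for interferon-stimulated genes, and 0 of the lists were called with an estimated correlation.

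All 13 lists called higher and 10 called lower rest on the preset correlation of 0.01, since 0 of 36 passed camera with an estimated correlation, 0 also at an unadjusted p under 0.05, while fry called 24. Genotype, sex and the share of neutrophil reads move together in these libraries, so none of the differences above is tied to one of them by the design.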

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

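The tests of explanations in this part and the covariate were chosen after the results were seen, while leaving out each library in turn, such as WT1, was planned. A value far from the other 3 of its group, by a gap above the 95% critical value of Dixon's test, was found in 16 of 340 groups of 4, where chance gives about 17. WT1 had the lowest log2(FPKM + 1) of Ly6g (0.77), Vcam1 (0.96) and Slc40a1 (0.29) and the highest of Mif (9.57) and Shmt2 (6.38) in WT. KO3, with the fewest reads, had the lowest of Mif (4.68), Trp53inp1 (2.57), Psat1 (3.09) and Il1b (3.05) in Nynrin-KO. KO1 had the highest Retnlg (10.82) and Xist (3.78), and KO4 the highest Hspa5 (9.56). WT2 had the lowest Arrdc1 (4.07) and the lowest share of summed FPKM from mitochondrially encoded mRNAs (6.57%), WT3 the lowest Ndfip2 (0.73), and WT4 the only Hbb-bs above 0 in WT (0.35).

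Chance assignment of libraries to groups was tested with the 35 splits of the 8 libraries. For the genes changed, 1 of 35 splits, the real one, reached 3488, and the highest of the others gave 271. The smallest share that 35 splits can give is 1 of 35. A split that mixes the groups also puts their difference into the spread within groups, which lowers its calls. This test by itself therefore cannot exclude chance. For lists called, 1 of 35 splits reached 23, but the highest of the others gave 18 with 0 genes changed. The split with 18, of WT1, WT2, WT4 and KO1 against the rest, swaps only 1 library of each group and so keeps part of their difference. Splits that balance the groups, such as WT1, WT2, KO1 and KO2 against the rest, called 0 to 11 lists. The preset correlation thus calls lists on balanced splits too, though fewer than on the real one. The count of lists sets the real split apart less than the count of genes.

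The fall of ribosomal protein genes had a median of -1.99. Dilution by RNA of mature neutrophils, as the whole source, would lower genes that these cells lack by about as much, but G2/M genes had a median of -0.44 (SD 0.37 over members), unless cycling itself rose in Nynrin-KO. A bias against short transcripts was argued against by a median of -1.78 (SD 0.233) left after a trend on transcript length. Sex stays open: KO1, with 11.8% of the Y-linked signal, lay at 105% of the way from the WT mean to the mean of KO2 to KO4, but a single library excludes nothing. Part of the fall may come from neutrophil RNA, since the median was -1.40 with the neutrophil score as a covariate, where the median SE grew from 0.284 to 0.345 and 0 of the 22 genes passed limma although camera still called the list, and the genotype stays open too.

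The rise of interferon-stimulated genes had a median of 3.08. With the neutrophil score as a covariate the median was 2.17 (SD 0.705 over members) and 0 of 22 passed, as the median SE grew from 0.608 to 0.854, while camera still called the list. A contribution of neutrophil RNA therefore cannot be told apart from the group, with which the score moves. Sex cannot be told apart either: KO1 lay at 68.4% of the way from the WT mean to the mean of KO2 to KO4. Over the lists scored this way, the position of KO1 ran from 28.9% for monocyte and macrophage genes to 140.8% for mature neutrophil genes. On the first principal component it was 91.5%. An interferon response that comes with the genotype stays open as a hypothesis.

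The rise of mature neutrophil genes had a median of 2.40. The low library WT1 alone does not account for it, since without WT1 the median was 1.41, 13 members rose and camera's adjusted p was 6.56e-08. If one population of neutrophils at a varying share were the only source of these RNAs, the members would keep a fixed ratio to S100a8. The median SD of that log2 ratio was 0.78 over 16 members, while S100a8 ranged over 6.64, and it ran from 0.13 for S100a9 to 1.42 for Csf3r. It was 0.25, 0.26, 0.38 and 0.47 for Camp, Ngp, Stfa2l1 and Ltf. For Cd177, Mmp8, Itgam, Retnlg, Cxcr2 and Csf3r it was 1.06 to 1.42. A ratio also varies where leukaemia cells express a member themselves, and joint maturation would also keep ratios fixed, so the test cannot decide. Carried-over neutrophils, which the Gr-1 gate should remove, and maturation of the leukaemia cells themselves therefore cannot be told apart.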

How the results depend on the processing

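Alternatives on the recovered reads, the libraries left out in pairs, the covariates and the libraries high in Gm10800 were chosen after seeing the data. Of 3338 values of named genes under the alternatives, 2939 stayed on their side of the threshold in the same direction, 339 lost and 58 gained significance, and 2 changed sign. Of 880 list values, 792 stayed, 75 lost and 13 gained a call. The causes were not tested unless stated. The genes changed, genes higher in Nynrin-KO and genes lower in Nynrin-KO were 1698, 790 and 908 with no filter and 1454, 671 and 783 at an adjusted p under 0.01. They were 1579, 765 and 814 without WT1 and KO1 (fewer libraries), 10, 5 and 5 with the neutrophil score as a covariate (which follows the group), and 925, 211 and 714 in the libraries high in Gm10800 (fewer libraries, and the cause was not tested). With an absolute log2 fold change of at least 1, 2128 genes changed and 969 were higher, and with a filter at 5 FPKM 1070 were higher (fewer genes tested). The gene list tests called 12 lists with that filter, 0 with an estimated correlation and 14 in the libraries high in Gm10800. Txnip log2 fold change passed with quantile normalization (1.162), array weights (0.923) and voom on recovered reads (0.749).

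With each library left out in turn, genes changed ranged from 2358 to 3606, genes lower in Nynrin-KO from 1204 to 1852, gene list tests from 19 to 23 and Txnip log2 fold change from 0.501 to 0.921. The genes higher in Nynrin-KO ranged from 1020 to 1875, with 1150 without WT1, 1048 without KO2 and 1020 without KO4. Nynrin log2 fold change ranged from -0.079 to 0.051, changing sign without WT1 (-0.072) and without KO3 (-0.079), with 2 to 37 reads per library. The replicate numbers did not consistently pair the libraries, as the values for same-numbered libraries were -0.213, -0.389, 0.329 and 0.008. These are not correlations of whole profiles, which ran from 0.712 to 0.904 between the groups. The best partners of WT1, WT2, WT3 and WT4 were KO4, KO3, KO3 and KO2, so WT3 alone matched its own number. With the replicate block, genes changed were 2838, with 1357 higher and 1481 lower, and 23 lists were called. Leaving out 1 library ended the call of the arrestin-domain list (WT2, WT4 or KO2), HECT list (WT3 or WT4), G2/M list (WT2, KO2 or KO3), quiescence list (WT2, WT3 or KO2), autophagy list (WT2 or WT3), unfolded protein list (KO3) and heat-shock list (KO1 or KO3). The filter at 5 FPKM ended the calls of the thioredoxin, arrestin-domain, HECT, NYN-domain, anti-apoptotic, G2/M, quiescence, unfolded protein and heat-shock lists. The neutrophil covariate also ended that of the mature neutrophil list, from which it is made. Fry did not call the G2/M and autophagy lists. It called 3 lists that camera did not, the stem and progenitor list as lower (fry adjusted p = 0.036) and the B cell and FOXO lists as higher (0.00867 and 0.00625). The alternatives planned for count tables were not run. Low depth in WT3 and KO3 limits genes under about 1.53 and 1.64 FPKM at 1 kb.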

Other observations

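Further families of the protein synthesis and folding machinery, grouped after the main result was seen, were lower in Nynrin-KO. All 5 elongation factor genes fell, with a median log2 change of -1.92, and Eef1a1 went from 6591 to 1513 FPKM. All 8 chaperonin subunit genes fell (median -1.54), as did 8 of 12 subunits of initiation factor 3 (median -1.10), 12 of 20 aminoacyl-tRNA synthetase genes (median -0.94), 19 of 37 proteasome subunit genes (median -0.88) and 28 of 76 mitochondrial ribosomal protein genes (median -0.63). None of these families had a member that rose. Each of these 6 families passed camera with the preset correlation, and each had an adjusted p = 0.312 with an estimated correlation. Of all 81 cytoplasmic ribosomal protein genes measured, a group not tested with camera, 79 fell and 0 rose, with a median of -1.90.

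Of 13 genes of MHC class I and its antigen processing 2 rose, H2-M3 and H2-Q7, with a median log2 change of 0.73 (camera adjusted p = 0.0346, adjusted p = 0.504 with an estimated correlation). The group includes Tap1, Tap2, Tapbp, Psmb8 and Psmb9, of which Psmb8 and Psmb9 also count among the proteasome subunit genes. Of 3 measured eosinophil-associated ribonuclease and granule genes 1 rose (camera adjusted p = 0.291, adjusted p = 0.504 with an estimated correlation). This was Ear2, which went from 1.64 to 33.5 FPKM, with 0.883 to 2.13 FPKM in WT and 25.8 to 40.3 FPKM in Nynrin-KO. Both groups were chosen after the main result was seen. Among genes on the X chromosome 30.0% were called, and among autosomal genes 27.8%.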
